A study of Homo sapiens with 24 samples.

How the data were processed

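Per the labels, naive and memory CD4 T cells were isolated from human donors by negative selection on magnetic beads, and CD8 T cells and CD19 B cells by positive selection. CD4 cells were kept in culture medium with beads carrying antibodies to CD3 and CD28 for 0 or 48 hours. After bisulfite conversion, genomic DNA was amplified in microdroplets with a custom library of primer pairs, in which primers over a CpG carried a degenerate base. The products were joined, sheared and sequenced. The submitters' processing notes name CASAVA, Novoalign and the human build hg18, without versions or roles. All positions are on hg18 as deposited.

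The deposited files hold 1 line per CpG, with read counts of each base on both strands and, for each strand, the methylation level as a fraction. The deposited counts are whole numbers and not normalised. The fraction, per the values deposited by the authors, is the methylated share of the informative reads of a strand, rounded down to 2 decimals, and could be recomputed from the counts at 99.998% or more of the CpGs of each library. The fraction was not used further. Methylated reads were counted here as cytosine on the forward and guanine on the reverse strand, unmethylated reads as thymine and adenine, and both strands were summed. Between 0.43% and 1.52% of base calls at CpGs were neither and were left out. Each file had 77674 lines, of which 531 repeated a CpG under another gene name and were merged, leaving 77143 positions. The 2777 CpGs on the sex chromosomes were left out of everything, which left 74366 CpGs. Of the 2127 gene names in the files, 2029 are current symbols and 96 older symbols in a RefSeq gene table of another assembly, which was used for names only. Whether a CpG lies in an exon, intron or untranslated region was not analysed here.

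Samples were grouped by cell type and activation from the labels: 5 libraries of resting memory, 4 of activated memory, 4 of resting naive and 3 of activated naive CD4 cells, and 4 each of CD8 and CD19 cells. The number that opens each label was taken as the donor and coded as replicates 1 to 7. That pairing rests on the labels alone and was not checked in the data, because donors were not matched by their sequence. At rest 4 donors gave both memory and naive cells, and after activation 3 did. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per CpG was 4.71, where noise alone gives about 1. The sequencing run, taken from the deposited files' names, was 1 of 4. Libraries held 4923730 to 53924266 informative base calls at CpGs, a median of 51 to 628 reads per CpG, and between 72.2% and 98.9% of CpGs with at least 20 reads. PCR reads without molecular identifiers are not independent molecules, so depth covers counting error only and the tests rest on the spread between libraries. The depth per strand reached at most 8053 reads, and a ceiling in the deposited counts cannot be excluded.

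CpGs with at least 20 reads in every library of a fit were tested with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood F test was run on methylated and unmethylated counts, with 1 coverage term per library and 1 methylation term per group. The 16 CD4 libraries were fitted together (58626 CpGs), as were the 17 libraries of resting CD4, CD8 and CD19 cells (52745 CpGs). A CpG was called at a Benjamini-Hochberg adjusted p under 0.05 and a difference of group means of at least 10 percentage points. The negative binomial dispersion was set to 0.01 with a trend on the methylation level, since a common dispersion estimated by edgeR called almost none of the simulated shifts. That choice was made on a first draw of simulated data: at dispersions of 0, 0.01, 0.02 and 0.05, shifts of 30 points in memory against naive cells at rest were recovered at 64.5%, 44.5%, 36.5% and 12.5%, with 13.1%, 5.57%, 4.46% and 3.50% of unchanged CpGs of intermediate level at an unadjusted p under 0.05.

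Regions were stretches of at least 3 CpGs with gaps of at most 500 bp (median length 303 bp in the CD4 fit). Their mean methylation was tested with limma 3.58.1 with a variance trend and called at an adjusted p under 0.05 and at least 5 points. Gene lists were compared with all other genes by camera in limma on gene means, with a preset correlation of 0.01. Genes were not matched by methylation level. Group means of whole libraries and of CpG sets were compared by two-sided exact permutation tests. Values of a named gene are means over its called CpGs, then over libraries; because the CpGs were chosen by the same test, these differences tend to be overstated. A cytosine to thymine variant at a CpG reads as unmethylated, and genotypes were not examined.

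The groups, tests, thresholds, gene lists and most alternatives were fixed before the data were examined. Named genes followed a rule: at least 2 CpGs called in 1 direction, each without overlap between the libraries of the groups, and among these the 12 genes with the largest mean difference in each direction, plus members of the 14 gene lists with a called CpG, of which up to 4 per list are named by size. The lists were effector molecules, chemokine receptors and homing, naive and quiescence, helper lineage transcription factors, activation and costimulatory receptors, T cell receptor signalling, cell cycle and DNA replication, growth and metabolism, DNA methylation machinery, interferon response, and markers of CD8 and cytotoxic, B, monocyte and granulocyte, and natural killer cells. Several lists were mostly not measured. The data held 3 of 20 CD8 and cytotoxic, 2 of 21 natural killer and 5 of 27 monocyte and granulocyte genes. They held 9 of 42 B cell and 5 of 21 DNA methylation genes, so results of these lists cover those members alone. Some further list members (GZMB, IL32 and IL22 at rest, PRF1 and CCL20 after activation, OAS2, GBP4, IFIT1 and the CD4 gene) and the values of AIM2, CCL3 and NOD2 in a state other than the one they were named for were chosen after their values were seen.

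The CpG tests were tried on simulated counts. These were drawn from the mean level of each CpG over all libraries of a fit, the spread within groups and the real depths. With 200 CpGs changed by each of 10, 20 and 30 points among 58626 CpGs, edgeR made at most 1 false call in each of the 4 CD4 comparisons of a second set of draws, against 2 in the draw used to choose the dispersion. For 30 points it recovered in the second set 41.5% for memory against naive at rest, 5.0% for memory against naive after activation, 30.5% for activation in memory and 13.5% for activation in naive cells. For CD19 against CD8 it recovered 6.5% of 200 among 52745 CpGs. Limma on percentages recovered 52.5%, 42.5%, 55.5%, 38.0% and 50.0% in these 5 comparisons and was added as an alternative. For regions, region means were simulated with normal noise of the spread within groups, for memory against naive cells at rest alone. Of 60 regions shifted by 10 points among 1953, 95% were recovered.

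Alternatives were coverage minimums of 10, 50 and 100 reads, limma on log2 ratios of methylated to unmethylated counts with 1 added to each, no minimum size or 20 points, the donor as a replicate block, only the groups compared, counts thinned to at most 100 reads, the run as a covariate, other region rules, an estimated correlation for camera, and leaving out each library in turn. Chosen after seeing the data were limma on percentages, only CpGs with a mean level of 5% to 95%, dispersions of 0 and 0.02, only the 2 runs that held both groups at rest, the replicate block with an estimated correlation for camera, and, for the CpGs read across cell types, leaving out single CD8 and CD19 libraries and an exact sign-flip permutation within the 4 donors of both. In all alternatives a named gene was followed at 1 leading CpG, its called CpG with the largest difference. Where at least 2 called CpGs had no overlap between the groups, it was the largest of these. The other called CpGs of the gene were not followed. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 read the files and drew the figures.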

Results

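Methylation of CpG sites was measured by targeted bisulfite sequencing in 24 samples of primary human lymphocytes. Bisulfite converts unmethylated cytosine, which is then read as thymine, so the share of cytosine among the informative reads at a CpG is its methylation level. Naive CD4 T cells, which have not yet met their antigen, and memory CD4 T cells, which descend from cells that have, were sampled at rest and 48 hours after activation with beads that engage CD3 and CD28. The CD4 libraries comprised 5 of resting memory cells, 4 of activated memory cells, 4 of resting naive cells and 3 of activated naive cells. CD8 T cells and CD19 B cells, not activated, gave 4 libraries each. The libraries came from 7 donors by the numbers in their labels, several of whom contributed more than 1 cell type. Each library held between 4923730 and 53924266 informative base calls at CpGs, and the median CpG had between 51 and 628 reads. Of the 74366 autosomal CpGs measured, 58626 CpGs in 1970 genes had at least 20 reads in every CD4 library and were tested there.

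The amplicons were mostly unmethylated in every cell type. Of the CpGs tested in the CD4 libraries, 93.5% had a mean methylation under 5%, and none of these, nor of those with a mean over 95%, was called between memory and naive cells at rest. Over the 48699 CpGs covered in all libraries, mean methylation was 4.18% ± 0.796 (SD, n = 5) in resting memory cells and 4.32% ± 0.852 (SD, n = 4) in resting naive cells. After activation it was 3.71% ± 0.234 (SD, n = 4) in memory cells and 3.69% ± 0.333 (SD, n = 3) in naive cells. CD8 cells had 5.07% ± 0.575 (SD, n = 4) and CD19 cells 4.78% ± 0.769 (SD, n = 4). None of 7 comparisons between these groups passed a two-sided exact permutation test. Memory against naive cells after activation and activation in naive cells could not pass, since their smallest possible p in this test was 0.0571. The largest difference, 0.825 percentage points between CD8 and resting CD4 cells, had an exact permutation p = 0.0979 and an adjusted p = 0.583.

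The first question was which CpGs distinguish memory from naive CD4 cells at rest. The largest difference lay at AIM2, a sensor of cytosolic DNA, whose 11 tested CpGs (hg18 chromosome 1, 157313001 to 157313800) averaged 18.9% ± 7.92 (SD, n = 5) in memory cells and 92.8% ± 2.48 (SD, n = 4) in naive cells. At IFNG, the gene of interferon gamma, both tested CpGs (chromosome 12, 66839843 and 66839975) averaged 41.6% ± 8.77 (n = 5) against 94.1% ± 2.79 (n = 4). CTLA4, an inhibitory receptor of T cells, averaged 29.1% ± 9.09 against 82.6% ± 4.91 over 2 CpGs (chromosome 2, 204441188 and 204441226), and the chemokine gene CCL5 40.1% ± 6.81 against 91.7% ± 1.62 over 7 CpGs (chromosome 17, 31231017 to 31231775). Fewer genes were more methylated in memory cells, among them LCK, the kinase that starts T cell receptor signalling, with 77.2% ± 11.3 against 32.9% ± 13.6 over 12 CpGs (chromosome 1, 32513682 to 32513810).

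In all, edgeR's quasi-likelihood test called 526 CpGs in 140 genes at an adjusted p under 0.05 and a difference of at least 10 percentage points. Methylation was lower in memory cells at 425 of them, in 117 genes, and higher at 101, in 27 genes. The direction varied with the mean level: 33 lower and 47 higher CpGs at 5% to 20%, 227 and 49 at 20% to 80%, and 165 and 5 at 80% to 95%. The median size of these differences was 25.7 percentage points. Over all CpGs tested, the memory and naive libraries did not overlap at 2.21%, against 1.59% by chance for groups of 5 and 4. The 11 AIM2 CpGs had edgeR adjusted p-values between 1.97e-10 and 2.04e-07, with a median of 428 reads per CpG and library and a lowest of 31. The IFNG CpGs, with a median of 74.5 reads, had edgeR adjusted p-values of 2.57e-06 and 0.000241. For LCK the adjusted p-values from edgeR ran from 5.52e-05 to 0.0283. Every memory library lay below, or for LCK above, every naive library in these gene means.

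Among the other genes with the largest reductions in memory cells were MEOX1 (51.1 points lower over 11 CpGs), ISG20 (49.1 points over 18 CpGs), SRGN (48.3 points), TRIM69 (44.8 points), PTPN7 (43.3 points over 16 CpGs), PSTPIP1 (43.1 points) and TNFSF14 (42.2 points). CCL3, a chemokine gene, was 54.5 points lower over 6 CpGs. Reads of near-identical neighbouring copies can be assigned to CCL3, so its value is uncertain, and the same holds for IFITM3. Higher methylation in memory cells was also found at RAC2 (40.1 points over 3 CpGs), IFITM3 (37.0 points over 8 CpGs), FLNB (26.8 points), DCHS1 (25.9 points), TRIP6 (25.5 points), SV2A (22.9 points), TNFSF15 (21.4 points), MPZL2 (20.8 points), FCER1G (20.3 points) and CD7 (19.7 points over 18 CpGs). ISG20 went both ways: 2 CpGs at 86982419 and 86982428 on chromosome 15 were 45.2 points higher in memory cells, while the 18 CpGs from 86983469 to 86983842 were lower.

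**Figure D1:**
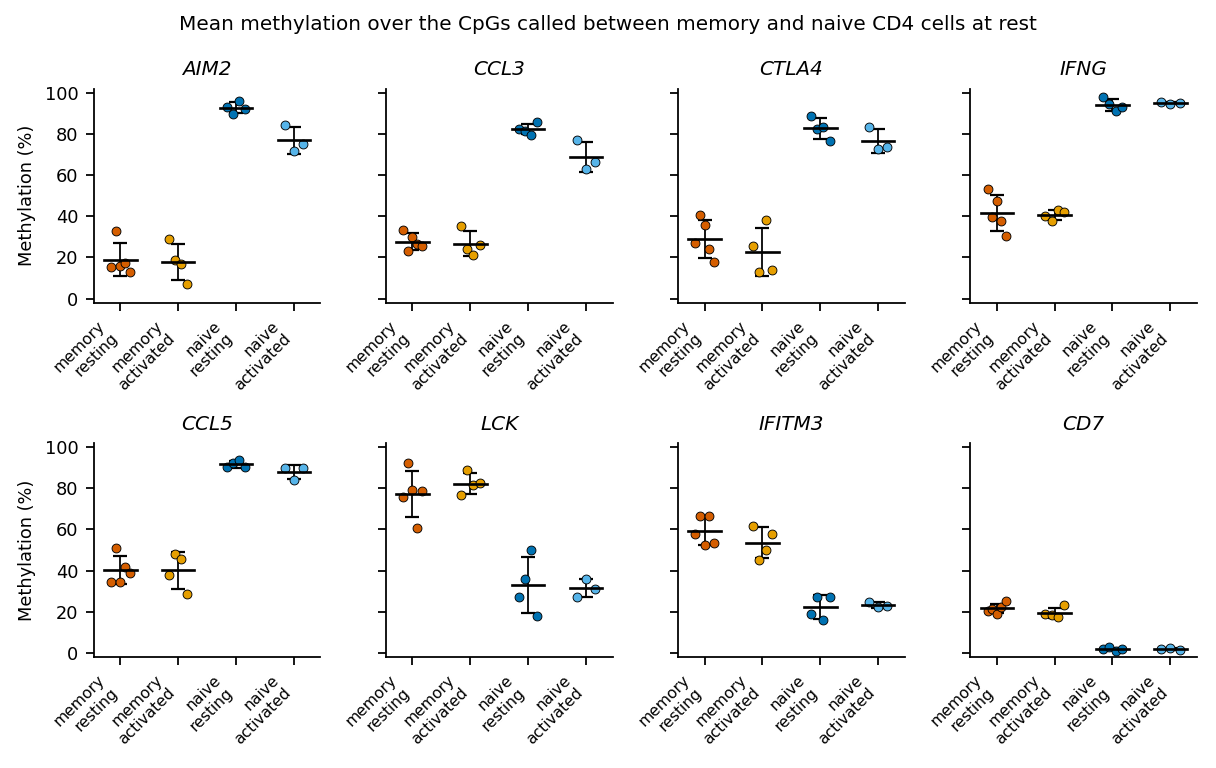
Methylation in percent (vertical axis) of 8 genes in the 4 CD4 groups (horizontal axis), as the mean over the CpGs called between memory and naive cells at rest. Each point is 1 library, the horizontal bar is the group mean and the error bar its SD; the 5 resting memory libraries lie below all 4 resting naive libraries for AIM2, CCL3, CTLA4, IFNG and CCL5 and above them for LCK, IFITM3 and CD7.

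Among the gene lists, effector molecules stood out most. Of 17 measured effector genes, 14 had CpGs lower in memory cells and none had higher ones, with a mean difference of -19.3 points over the genes. Besides IFNG, CCL5, CCL3 and TNFSF14 these included GZMB, the gene of granzyme B (59.1% ± 7.90 against 94.5% ± 2.64), IL32 (55.9% ± 13.9 against 94.1% ± 1.89) and the cytokine gene IL22 (59.7% ± 4.94 against 89.4% ± 1.65). Limma's camera test placed the list lower than other genes with an adjusted p = 2.24e-35, and with adjusted p = 1.33e-07 under an estimated correlation. At edgeR's threshold 58 of its 185 CpGs were called over all CpGs tested and 74 when adjusted over the list alone. Camera compared the list with all other genes, and 93.5% of the CpGs tested had a mean level under 5%. Among all tested CpGs, 28.9% of those at a mean level of 20% to 80% were called, and 27.5% of those at 80% to 95%. The list result may therefore reflect the level of its CpGs, which was not tested. All 3 measured genes of the 20 on the CD8 and cytotoxic list were lower. They were CCL5, PRF1, the gene of perforin (61.2% ± 4.34 against 89.6% ± 1.25), and RUNX3 (4.19% ± 1.84 against 16.5% ± 2.70). The list had a camera adjusted p = 9.23e-10 and, with an estimated correlation, adjusted p = 0.000199. CCL5 and PRF1 are on the effector list too. All 4 measured genes of the monocyte and granulocyte list were also lower, MPO, ITGAX, S100A8 and LYZ, by 32.6, 29.7, 20.1 and 16.9 points (camera adjusted p = 1.6e-09, and adjusted p = 0.000481 with an estimated correlation).

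Of 19 measured chemokine receptor and homing genes 8 had lower CpGs, led by ITGB7 (39.9 points), ITGB2 (39.9 points), LGALS1 (32.9 points) and S100A4 (14.8 points). The camera call of this list (adjusted p = 1.21e-06) was lost with an estimated correlation (adjusted p = 0.161). Both measured genes of the 21 on the natural killer list, FCER1G and CD7, were higher. Their camera call (adjusted p = 0.0165) was also lost with an estimated correlation (adjusted p = 0.0594). CD7 is also carried by most T cells. Counted over all CpGs tested and then adjusted over the list alone, the called CpGs were 28 and 37 for homing genes, 19 and 24 for the CD8 and cytotoxic list, 15 and 19 for the monocyte and granulocyte list, and 23 and 33 for the natural killer list.

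The other lists did not pass camera's test as groups at rest, though single members did by edgeR. Interferon response genes went both ways: of 13 measured genes 5 had lower CpGs, among them ISG20, OASL and OAS2, and 4 had higher ones, IFITM3, GBP4, IFIT1 and ISG20 (camera adjusted p = 0.162; 44 CpGs called, and 52 adjusted over the list alone). Of 17 activation and costimulatory receptors 6 were lower, among them CTLA4 and ICOS (61.1% ± 3.68 against 92.9% ± 3.56), with a camera adjusted p = 0.174 (11 CpGs called, and 12 adjusted over the list alone). Of 23 helper lineage transcription factors 3 were lower, RORC, STAT4 and RUNX3, with 14 CpGs called either way (camera adjusted p = 0.402). The CD4 gene itself was lower in memory cells, with 38.5% ± 4.26 against 68.7% ± 1.56 over 6 CpGs, and with LCK it was 1 of 2 genes called among 30 of T cell receptor signalling (camera adjusted p = 0.692; 18 CpGs, and 21 adjusted over the list alone). Of 17 naive and quiescence genes SATB1 was higher and TOB1 lower (camera adjusted p = 0.242; 3 CpGs either way), and of 8 B cell genes CD74 and CIITA were lower (camera adjusted p = 0.236; 4 CpGs, and 5 adjusted over the list alone). None of the 40 cell cycle, 22 growth and metabolism and 5 DNA methylation genes measured held a called CpG, also when adjusted over the list alone (camera adjusted p = 0.685, 0.905 and 0.980).

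Averaged over stretches of CpGs, 89 of 1953 regions differed by limma at an adjusted p under 0.05 and at least 5 points, 71 lower and 18 higher in memory cells. Within the 2 sequencing runs that held both cell types, whose libraries were among those the CpGs were called on, the lower and higher CpGs had median differences of -28.0 and 21.2 points in one and -23.8 and 26.2 points in the other. In simulated data edgeR recovered 41.5% of shifts of 30 points and 0.5% of shifts of 10 points in this comparison, so CpGs with smaller differences were mostly not detectable. With the donor as a replicate block the calls of DCHS1, IFIT1 and RUNX3 were lost (edgeR adjusted p = 0.0694, 0.0501 and 0.0932 at the leading CpG).

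The same contrast was then made 48 hours after activation. NOD2, an intracellular sensor of bacterial cell wall, had the largest difference: over 4 CpGs (chromosome 16, 49287647 to 49289272) activated memory cells averaged 24.3% ± 5.03 (SD, n = 4) and activated naive cells 96.3% ± 1.08 (SD, n = 3). The resting values at those CpGs were 33.2% ± 7.65 (n = 5) and 95.9% ± 1.76 (n = 4), and 9 NOD2 CpGs were called at rest. AIM2 averaged 19.3% ± 9.66 against 82.6% ± 5.90 over 10 CpGs, IFNG 40.7% ± 2.34 against 94.9% ± 0.610, CTLA4 22.7% ± 11.8 against 76.5% ± 5.99, and CCL5 45.5% ± 9.62 against 95.3% ± 1.78 over 6 CpGs. LCK was again higher in memory cells, with 82.3% ± 5.83 against 31.5% ± 4.16 over 12 CpGs, and ABCA1, a cholesterol exporter, had 59.9% ± 13.3 against 16.5% ± 2.84 over 3 CpGs (chromosome 9, 106730564 to 106730593).

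By edgeR 225 CpGs in 71 genes passed, 174 lower and 51 higher in memory cells, with a median size of 39.1 points. Over all CpGs tested, the libraries did not overlap at 5.27%, against 5.71% by chance for groups of 4 and 3. The 4 NOD2 CpGs had edgeR adjusted p-values between 9.34e-08 and 2.11e-05, with a median of 383.5 reads per CpG and library. Of the CpGs called at rest, 517 of 526 had the same direction after activation and 438 differed by at least 10 points the same way. Called in both states were 167 lower and 35 higher CpGs, against 23.6 and 1.65 for independent lists among the 3128 CpGs with a mean level of 5% to 95%, which held all calls of both states. These comparisons used different libraries, partly of the same donors. Within the 2 runs, whose libraries are those the CpGs were called on, the lower and higher CpGs had median differences of -41.8 and 35.8 points in one and -38.9 and 29.3 points in the other, which held a single activated naive library. The count rested in part on single libraries: it was 147 without memory replicate 6, 142 without naive replicate 6 and 139 without naive replicate 3. It was 515 when only CpGs with a mean level of 5% to 95% were tested, and in simulations of all CpGs edgeR recovered 5% of shifts of 30 points here, so many differences of that size could be missed. The leading CpG of ABCA1 was no longer called without naive replicate 6 (edgeR adjusted p = 0.0669), nor was that of IFNG without naive replicate 3 (0.0604). Of the leading CpGs of 42 named gene results of this contrast, 15 were lost without naive replicate 6, 14 without naive replicate 3 and 12 without memory replicate 6. Regions gave 71 calls by limma, 53 lower and 18 higher.

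The gene lists, again not matched by methylation level, repeated much of the resting order. Of 17 effector genes 10 had lower CpGs, IL32 (62.5 points at 1 CpG), GZMB (50.9 points at 1 CpG), PRF1 (41.9 points at 1 CpG) and CCL20 (29.1 points at 2 CpGs) among them (camera adjusted p = 8.93e-35, and adjusted p = 1.47e-07 with an estimated correlation; 22 CpGs called, and 61 adjusted over the list alone). The CD8 and cytotoxic list (2 of 3 genes lower; adjusted p = 2.33e-09, and 0.000246 as the adjusted p with an estimated correlation) and the monocyte and granulocyte list (3 of 4 genes lower; adjusted p = 3.25e-08, and 0.000983 as the adjusted p with an estimated correlation) passed camera as well. So did the natural killer genes CD7 and FCER1G, which were higher (adjusted p = 0.00404, and adjusted p = 0.0264 with an estimated correlation). Adjusted over the list alone, 18, 11 and 30 CpGs of these 3 lists were called, against 7, 7 and 10 over all CpGs. Camera calls of chemokine receptor and homing genes (adjusted p = 0.00226), activation receptors (0.0173) and interferon response genes (0.0303), all lower, and of naive and quiescence genes, higher (0.0135), were lost with an estimated correlation (adjusted p = 0.434, 0.450, 0.356 and 0.598). Called members of these lists were ITGB2, LGALS1 and S100A4 for homing, CTLA4, ICOS and IL1R2 for activation receptors, and SATB1 for naive genes. The interferon list had 2 lower genes, ISG20 and OASL, and 2 higher ones, IFITM3 and GBP4. With the donor as a replicate block the call of the interferon list was lost (camera adjusted p = 0.249). So were those of the leading CpGs of SATB1, FCER1G and S100A4 (edgeR adjusted p = 0.0672, 0.0726 and 0.0642). Adjusted over the list alone, these 4 lists had 13, 8, 45 and 2 called CpGs, against 11, 4, 25 and 2 over all CpGs. The remaining lists did not pass camera after activation: helper transcription factors (RORC lower; adjusted p = 0.452), T cell receptor signalling (CD4 lower, LCK higher; 0.441), B cell (CIITA lower; 0.174), cell cycle (0.798), growth and metabolism (0.878) and DNA methylation genes (0.531).

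The next question was whether 48 hours of activation changed methylation within each CD4 cell type. AIM2 was at 17.9% ± 8.87 (n = 4) in activated memory cells over the 11 CpGs above, against 18.95% ± 7.92 (n = 5) at rest. In naive cells it was at 76.9% ± 6.55 (n = 3) after activation, against 92.77% ± 2.48 (n = 4) at rest. That difference in naive cells was not called, also not as a region. The corresponding CCL3 values were 26.7% ± 6.21 in memory and 68.6% ± 7.33 in naive cells over 6 CpGs, against 27.7% ± 4.10 and 82.2% ± 2.49 at rest. Adjusted over all CpGs tested, single CpGs did not pass edgeR's test in either cell type. In memory cells edgeR called 0 CpGs (4056 with an unadjusted p under 0.05, 6.92% of those tested; smallest adjusted p = 0.673), and limma called 0 both on log2 ratios and on percentages. In naive cells edgeR called 0 CpGs (3779 with an unadjusted p under 0.05, 6.45%; smallest adjusted p = 0.210), limma on log2 ratios called 0 and limma on percentages 1, lower after activation. Adjusted over a gene list alone, edgeR called 1 CpG in 1 effector gene in naive cells and 0 CpGs of every other list in both cell types. For the difference between the 2 activation responses edgeR called 0 as well (2860 with an unadjusted p under 0.05; smallest adjusted p = 0.988), as did limma on log2 ratios and on percentages. In simulations edgeR recovered 30.5% of shifts of 30 points in memory cells and 13.5% in naive cells, so differences of that size at single CpGs could be missed.

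Averaged over regions, limma called 0 of 1953 regions in memory cells (55 with an unadjusted p under 0.05) and 4 in naive cells. In naive cells CCL3 fell by 12.9 points over 7 CpGs (chromosome 17, 31441533 to 31442142), MEOX1, a homeobox gene, by 9.44 points over 5 CpGs (chromosome 17, 39095567 to 39095733) and AGER by 6.70 points over 6 CpGs (chromosome 6, 32259027 to 32259967). LSP1, an actin-binding protein of leukocytes, rose by 9.91 points over 29 CpGs (chromosome 11, 1848810 to 1849130). The same regions differed by -1.47, 4.51, -1.74 and -0.12 points in memory cells. With the donor as a replicate block 0 regions were called, and the count was 0 without activated naive replicate 4 or resting naive replicate 1, and 2 without replicate 3 of either state. Averaged over all tested CpGs of a gene, limma with no minimum difference had 3 of 1970 genes lower after activation in naive cells, 0 with the replicate block, and 0 in memory cells. None of the 14 gene lists passed camera in memory or naive cells; with the replicate block the monocyte and granulocyte list passed in memory cells (adjusted p = 0.0383), and not with an estimated correlation (adjusted p = 0.564).

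CD19 B cells were then compared with CD8 T cells. CD2, a T cell adhesion receptor, averaged 94.2% ± 1.57 (SD, n = 4) in CD19 cells and 10.6% ± 6.61 (SD, n = 4) in CD8 cells over all 7 tested CpGs (chromosome 1, 117099376 to 117099494). CD7, a T cell and natural killer surface protein, averaged 89.8% ± 1.89 against 17.8% ± 3.00 over 35 CpGs (chromosome 17, 77867755 to 77869012), and LSP1 84.0% ± 4.04 against 19.9% ± 6.74 over all 29 CpGs. The perforin gene PRF1 had 93.6% ± 2.53 against 40.1% ± 9.46 over 8 CpGs. Less methylated in CD19 cells were SLFN13, with 2.51% ± 1.96 against 71.3% ± 10.8 over 5 CpGs (chromosome 17, 30800666 to 30800686), MPEG1, which encodes perforin-2, with 47.1% ± 14.1 against 91.9% ± 2.11 over 7 CpGs (chromosome 11, 58736202 to 58736952), and CRIP1 with 9.85% ± 1.05 against 49.9% ± 4.52 over 20 CpGs.

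Of 52745 CpGs tested in 1946 genes, edgeR called 262 in 61 genes, 124 higher and 138 lower in CD19 cells, with a median size of 46.4 points. Over all CpGs tested, the libraries did not overlap at 3.13%, against 2.86% by chance for groups of 4. The CD7 CpGs had edgeR adjusted p-values from 6.16e-13 to 0.00299, with a median of 274 reads per CpG and library. Further genes with higher methylation in CD19 cells were IL32 (74.5 points), PSTPIP1 (50.9 points), ITGB2 (48.3 points), CCR7 (37.3 points) and SH2D2A (36.7 points). Lower ones were CD244 (58.0 points), CAMP (54.8 points), RAC2 (53.0 points), IL1R2 (49.7 points), TPM2 (43.5 points over 11 CpGs) and FLT1 (42.5 points). The count was 437 when only CpGs with a mean level of 5% to 95% were tested, and in simulations edgeR recovered 6.5% of shifts of 30 points. Regions gave 60 calls by limma, 22 higher and 38 lower.

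Camera placed 3 lists higher in CD19 than in CD8 cells: natural killer genes (CD7 called, FCER1G not; adjusted p = 6.37e-06, and adjusted p = 0.00846 with an estimated correlation), the CD8 and cytotoxic list (PRF1 the only 1 of 3 genes called; adjusted p = 0.000654, and adjusted p = 0.0115 with an estimated correlation), and naive and quiescence genes, CCR7 and TOB1 (adjusted p = 0.00789, lost with an estimated correlation at adjusted p = 0.688). Adjusted over the list alone these had 36, 13 and 8 called CpGs, against 35, 8 and 6 over all CpGs. Of the 42 B cell genes listed 8 were measured, and none of these held a called CpG, also when adjusted over the list alone (camera adjusted p = 0.0777). Of 15 effector genes 2 were higher and 2 lower (camera adjusted p = 0.196), and of 18 homing genes ITGAE, ITGB2 and LGALS1 were higher (0.0548, and adjusted p = 0.0378 with the donor as a replicate block). Activation receptors had CD2, CD226 and TNFRSF25 higher and CD244 and IL1R2 lower (0.0846). The other lists had camera adjusted p-values between 0.351 and 0.887. With the donor as a replicate block and an estimated correlation together, no list passed, and the natural killer and the CD8 and cytotoxic lists both had a camera adjusted p = 0.0567.

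**Figure D2:**
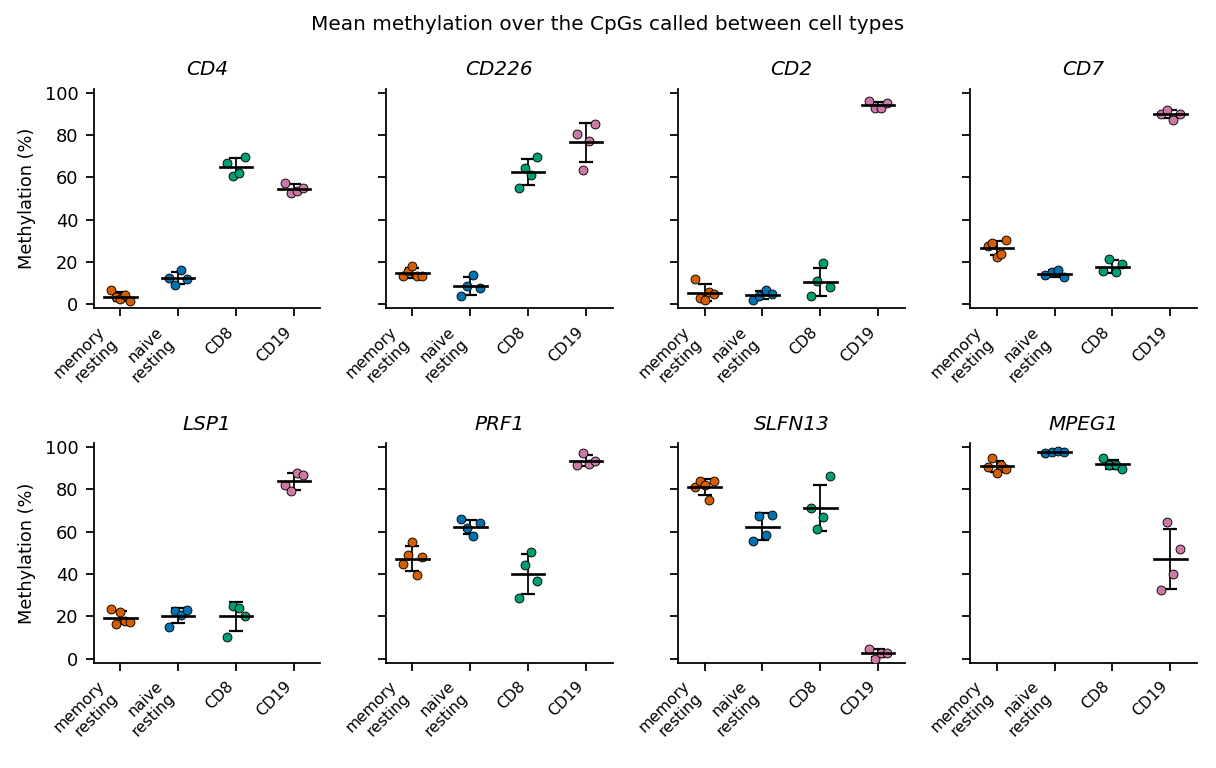
Methylation in percent (vertical axis) of 8 genes in resting memory CD4, resting naive CD4, CD8 and CD19 cells (horizontal axis), as the mean over the CpGs called higher in CD8 than resting CD4 cells (CD4, CD226), or called between CD19 and CD8 cells (the other genes). Each point is 1 library, the horizontal bar is the group mean and the error bar its SD; CD19 libraries average 94.2% at CD2 and 2.51% at SLFN13.

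Against resting CD4 cells, CD8 cells were more methylated at the CD4 gene: its 11 called CpGs (chromosome 12, 6768907 to 6769991) averaged 64.7% ± 4.23 (SD, n = 4) in CD8 cells and 7.49% ± 5.08 (SD, n = 9) in CD4 cells. CD226, an activating receptor of T and natural killer cells, averaged 62.5% ± 6.23 against 12% ± 4.44 over 6 CpGs (chromosome 18, 65774813 to 65775138), and the imprinted gene NNAT 84.0% ± 3.77 against 42.2% ± 14.2 over 15 CpGs. The cytotoxic gene PRF1 was lower in CD8 cells (22.5% ± 1.58 against 60.2% ± 16.4 at 1 CpG). CCL5, called lower over 3 CpGs, averaged 61.5% ± 13.6 in CD8 cells (n = 4), 58.9% ± 8.19 in memory cells (n = 5) and 97.4% ± 1.84 in naive cells (n = 4), so it was below naive but not memory CD4 cells. By edgeR 73 CpGs in 32 genes passed, 65 higher and 8 lower in CD8 cells, and the CD4 gene had edgeR adjusted p-values from 8.63e-11 to 0.00615. The CD8 and CD4 libraries did not overlap at 0.89% of all CpGs tested, against 0.28% by chance. All CD8 and CD19 libraries came from 1 sequencing run that held no CD4 cells. Of the CpGs higher and lower in CD8 cells, 6 and 3 were also called the same way against CD19 cells within that run, and 2 and 0 the opposite way. The count was 22 with the donor as a replicate block and 23 without CD8 replicate 7, and 187 when only CpGs with a mean level of 5% to 95% were tested. The block ended the calls of the leading CpGs of NNAT, PRF1 and CCL5 (edgeR adjusted p = 0.151, 0.0684 and 0.207).

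CD19 cells differed from resting CD4 cells at 465 CpGs in 130 genes by edgeR, 286 higher and 179 lower in CD19 cells. The CD19 and CD4 libraries did not overlap at 1.24% of all CpGs tested, against 0.28% by chance. CD2 averaged 94.2% ± 1.57 (n = 4) against 5.00% ± 3.07 (n = 9), CD226 76.6% ± 9.21 against 12% ± 4.44, and the CD4 gene 62.9% ± 2.10 against 14.7% ± 6.06 over 11 CpGs. SLFN13 (62.4 points), CAMP (58.0 points) and MPEG1 (44.0 points over all 9 CpGs) were lower in CD19 cells. The adjusted p-values of CD2 from edgeR ran from 1.89e-13 to 2.58e-08. This comparison and that of CD8 cells share the 9 CD4 libraries, which came from other runs. Of the 465 CpGs, 234 were also called the same way between CD19 and CD8 cells, whose libraries shared 1 run, and 0 the opposite way. CD8 cells lay near CD4 cells at CD2 (10.6% ± 6.61, n = 4), SLFN13 (65.1% ± 9.92, against 66.5% ± 11.4 in CD4 cells) and CAMP (91.3% ± 3.12, against 94.1% ± 5.27), so the run alone did not give these differences. At the CD4 gene, where CD8 cells had 71.2%, the run and the cell type cannot be told apart.

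Finally, the CpGs that distinguish memory from naive CD4 cells were read in the other lymphocytes. At the 272 CpGs lower in memory cells that were covered in all libraries, CD8 cells averaged 69.5% ± 3.50 (n = 4) and CD19 cells 69.2% ± 2.97 (n = 4), between the 49.0% ± 1.59 (n = 5) of resting memory and the 79.3% ± 0.489 (n = 4) of resting naive cells, the groups on which the CpGs were chosen. The difference between CD8 and CD19 cells was 0.27 points (two-sided exact permutation p = 0.943). At the 67 CpGs higher in memory cells, CD8 cells averaged 38.4% ± 5.15 and CD19 cells 43.8% ± 3.34, a difference of -5.36 points (exact permutation p = 0.143, where the smallest possible is 0.0286). The 4 donors were the same for both, and CD8 cells were below CD19 cells in all 4 (exact permutation p = 0.125 within donors, the smallest possible). With at least 100 reads the difference was 7.05 points (exact permutation p = 0.0857), the other way round, so its direction was not settled. Activated memory and naive cells averaged 50.4% ± 1.15 (n = 4) and 75.4% ± 0.441 (n = 3) at the first set, and 44.7% ± 1.10 and 19.4% ± 2.19 at the second.

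**Figure D3:**
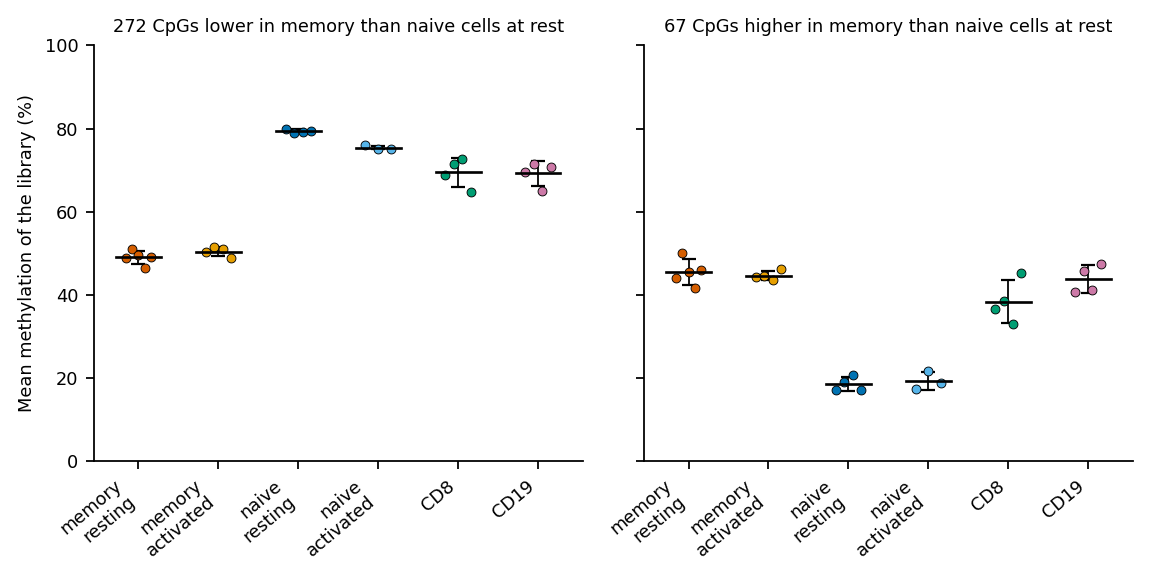
Mean methylation in percent (vertical axis) of each library over the 272 CpGs lower and the 67 CpGs higher in memory than naive CD4 cells at rest, by group (horizontal axis). Each point is 1 library, the horizontal bar is the group mean and the error bar its SD; at the CpGs lower in memory the CD8 and CD19 libraries lie between 64.8% and 72.7%, between memory and naive CD4 cells.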

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

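The thinned-count tests of the memory and CD8 patterns below and the CD8 calls within 1 run were tests chosen after the result was seen. For CD8 or CD19 cells in the memory fractions, the bounds set beforehand covered the median share alone. The quartiles and the comparison of single memory, CD8 and CD19 libraries were not part of them.

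In 3 of 110 groups of 4 or 5 libraries, 1 library stood far from the others of its group. Chance alone gives about 1 in 20 such groups, and 2.7% were found. At the AIM2 CpGs lower in memory, resting memory replicate 3 had 32.86%, against 17.5% in the nearest other library. Resting memory replicate 5 had 14.83% at the ISG20 CpGs lower in memory, where the nearest other library had 25.22%. Resting naive replicate 1 had 86.11% at the CCL3 CpGs lower in CD19 than CD4 cells, against 78.59% in the nearest.

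At rest 425 of 526 called CpGs were lower in memory than in naive cells. Unequal bisulfite conversion is argued against by the CpGs under 5% methylation, where the naive minus memory difference was -0.003 points (1.767% ± 0.797 in 5 memory and 1.764% ± 0.857 in 4 naive libraries). CD8 or CD19 cells in the memory fractions could lower methylation there. At CpGs higher in CD8 than in CD4 cells, memory lay above naive by a median of only 4.18% of the distance (quartiles -4.67% to 23.38%). At CpGs higher in CD19 than in CD4 cells the median was 2.36% (-16.81% to 13.45%). At the 272 CpGs lower in memory, which were chosen on these memory libraries, no memory library exceeded 50.95%. No CD8 library was under 64.83% there and no CD19 library under 64.93%. Adding cells at the level of these libraries to naive cells therefore cannot give the memory level. A subset of CD8 or CD19 cells with lower methylation than the whole, and other cell types such as monocytes, were not tested. Run and depth are argued against too, since 100% of the 225 CpGs called after activation had the same direction among the resting libraries of run 88, and 80% of the calls were lower in memory with counts thinned to 100 reads. A difference between memory and naive cells themselves, which the design names, stays open. The CpGs called at rest were found and tested on the same libraries. The 225 CpGs called after activation came from other runs than run 88 and, by the labels, other donors. Their median difference was 41.34 points in run 88, against 39.06 after activation. The fit that called them shared its estimate of spread over all CD4 libraries.

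Of 73 CpGs called between CD8 and resting CD4 cells, 65 were higher in CD8. A higher background is argued against as the source, because at CpGs under 5% methylation CD8 lay only 0.595 points above CD4 cells (2.355% ± 0.569, n = 4, against 1.76% ± 0.77, n = 9), and so is unequal depth, because 90.2% of the calls were higher in CD8 with thinned counts. The sequencing run could shift these CpGs, since no CD4 library shared the run of the CD8 libraries. In the CD19 libraries of that run, 49 of the 65 CpGs (75.4%) were shifted by more than 50% of the CD8 shift (median 15.62 points, against 30.93 in CD8), and both comparisons share the CD4 libraries. At 6 of the 65 CpGs CD8 was also called higher than CD19 within that run, which argues against the run as the whole source there. At 2 CpGs CD8 was called lower than CD19 within the run. At the 59 CpGs other than those 6, these 2 among them, run and cell type cannot be told apart. A difference between the cell types stays open.

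The 4 regions called between activated and resting naive cells could reflect different donors or sequencing runs in the 2 groups. Run 88 held 2 of the resting and none of the activated naive libraries. Another run held 1 activated and no resting naive library. The run was a covariate for CpGs only, not for regions. Donors and runs cannot be told apart from activation. All 4 moved the called way by more than 50% of the called difference within the 2 donors who gave both libraries, but those 4 libraries are among the 7 on which the regions were called, so the outcome was largely fixed. No region was called with the donor as a replicate block, and 0 were called without activated replicate 4 or resting replicate 1. With the block the limma estimates (± moderated standard error, n = 3 and 4) went from -12.93 ± 2.31 to -10.75 ± 2.55 points for CCL3 and from -9.44 ± 2.26 to -10.81 ± 2.61 for MEOX1. They went from -6.70 ± 1.57 to -4.45 ± 1.49 for AGER and from 9.91 ± 2.02 to 10.66 ± 2.72 for LSP1. These errors borrow variance from the fit of all CD4 libraries and other regions. The SDs of the activated and resting naive libraries themselves were 7.12 and 2.23 points for CCL3 and 4.41 and 3.12 for MEOX1. They were 3.58 and 2.11 for AGER and 7.29 and 3.75 for LSP1. The calls ended because limma's p-values rose, to between 0.000728 and 0.0093, which missed the threshold once adjusted over 1953 regions (limma adjusted p = 0.557 to 0.576). Chance is not excluded: another split of the 7 libraries gave 5 regions. Activation itself, which the design names, stays open.

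Chance was argued against for 8 results with the donor pairing ignored, counting how often other splits into groups of the same sizes gave as many calls. No other split counted did so, except for CD8 against resting CD4 cells, where 1 of 59 did. With the pairing kept, chance was not excluded for memory against naive or CD19 against CD8 cells. Only 7 to 14 other splits counted there part as many donor pairs, too few to decide, though none gave as many calls. For memory against naive at rest, 60 splits were counted for CpGs (526 calls against at most 234 in another split) and 100 for regions (89 against 60). The 8 other splits that part as many donor pairs reached 234 CpGs, those that part fewer 135, and a split along the run 4. After activation the counts were 225 CpGs against 104 and 71 regions against 31, over all 35 splits; the splits that part fewer of the 3 pairs reached 0 CpGs. In both states the highest other split put 1 memory library with all the naive libraries and so kept most of the real division. For CD19 against CD8 they were 262 CpGs against 0 and 60 regions against 2, and for CD19 against resting CD4 cells 465 CpGs against 127. For CD8 against resting CD4 cells 73 CpGs were called, while 1 of 59 other splits, which set 4 memory libraries against the rest, called 128 and so followed the memory to naive difference; the split with 127 was of the same kind.

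For the activation results chance was not excluded even with the pairing ignored. They were, in calls of the real split against the highest other, 0 against 0 CpGs and 0 against 5 regions in memory cells, 0 against 2 CpGs and 4 against 5 regions in naive cells, and 0 against 3 CpGs for the difference between the responses. Among splits that part as many of the donor pairs, the highest was 2 regions in memory cells and 1 in naive cells.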

How the results depend on the processing

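Limma on percentages, CpGs of 5% to 95% mean methylation, dispersions of 0 and 0.02, the 2 runs with both resting groups, leaving out CD8 or CD19 libraries or pairing them by donor at the memory CpGs, and the block with an estimated correlation were tests chosen only after the result was seen. No called result reversed. Memory against naive cells at rest gave 412 to 732 CpGs under the alternatives other than those given next. Causes were not tested, except that a higher coverage minimum leaves fewer CpGs and a larger minimum difference admits fewer calls.

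With at least 50 reads the CpG counts were 287 (main 526) for memory against naive at rest, 126 (225) after activation, 34 (73) for CD8 and 265 (465) for CD19 against resting CD4 cells; with at least 100 reads they were 109, 44, 19 and 112, and 98 (262) for CD19 against CD8. With a minimum of 20 points they were 331 at rest and 45 for CD8 against CD4. For the latter, limma on log2 ratios gave 126, thinned counts 132, limma on percentages 171 and CpGs of 5% to 95% methylation 187. That last choice gave 515 for memory against naive after activation and 437 for CD19 against CD8. Activation in naive cells gave 1 CpG (main 0) with thinned counts, limma on percentages, CpGs of 5% to 95% methylation or a dispersion of 0.

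With the donor as a replicate block the counts were 533 CpGs at rest, 196 after activation, 0 for each activation contrast, 275 for CD19 against CD8, 387 for CD19 and 22 (19 higher) for CD8 against CD4. The block gave 91, 70, 0, 0 and 68 regions in the order of the report; that for activation in naive cells lost all 4. It added 1 gene list (main 0) in memory activation, at which the test pointed up while the mean was -0.404 and the median 0.4 points, and it moved the CD8 minus CD19 difference at CpGs lower in memory from 0.27 to -0.12 points. It ended the interferon list call after activation and added the homing list for CD19 against CD8. It also ended the call of the leading CpG in 28 of 205 named gene results. With the preset correlation for lists it changed no other call of the leading CpG of a named gene, or of a named region or list. An estimated correlation left 3 of 5 lists at rest and 4 of 8 after activation, without the block and with it, and with the block 0 of 3 for CD19 against CD8 (2 without it).

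Regions in naive activation were 1 with gaps of at most 200 bp and 0 at 50 reads. Averaged within regions first, mean methylation differed by -0.234 points (main 0.02) between activated memory and naive cells, and by 1.046 points (main 0.825) between CD8 and CD4 cells, which then passed the exact permutation test (p = 0.042, unadjusted). At 100 reads the CD8 minus CD19 difference at CpGs higher in memory was 7.05 (main -5.36) points, with an exact permutation p = 0.0857.

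Leaving out 1 library at a time gave 451 to 520 CpGs at rest, 139 to 235 after activation (147 without memory replicate 6, 142 without naive replicate 6, 139 without naive replicate 3), 0 in each activation contrast, 213 to 252 for CD19 against CD8, 357 to 483 for CD19 and 23 to 91 for CD8 against CD4 cells (23 without CD8 replicate 7). Regions were 0 to 2 in memory activation (1 without resting replicate 3 or activated replicate 6, 2 without resting replicate 6) and 0 to 5 in naive activation (0 without activated replicate 4 or resting replicate 1, 2 without replicate 3 of either state). Mean methylation differed by -0.426 to 0.225 points at rest, -0.079 to 0.212 after activation and -0.496 to 0.069 between CD19 and CD8 cells. The CD8 minus CD19 difference at CpGs lower in memory ran from -1.16 to 1.81.

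Of 4559 values at the leading CpGs of 205 named gene results, 4160 stayed past the threshold and 399 did not, with none reversed. Of 210 for gene lists, 191 did not change side. CpGs under 20 reads in any library of a fit were not tested, so depth limits which CpGs were open to a call.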

Other observations

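No test in this part was chosen after its result was seen, though the genes named in it were.

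Further cytokine genes on the effector list held CpGs that were less methylated in resting memory cells. IL21 had 70.8% ± 9.43 (SD, n = 5) in memory and 98.5% ± 0.98 (SD, n = 4) in naive cells at 1 CpG, and IL13 78.2% ± 5.20 against 97.7% ± 0.38 over 6 CpGs. For IL17A the levels were 83.8% ± 2.48 and 98.4% ± 0.88 over 5 CpGs, for IL17F 87.0% ± 5.33 and 98.6% ± 0.90 over 2, and for IL10 83.2% ± 4.92 and 96.3% ± 2.31 over 1. RORC, which directs the lineage that makes IL-17, had 72.8% ± 6.99 against 97.6% ± 0.30 over 8 CpGs, with edgeR adjusted p-values as low as 1.33e-07. After activation IL13, IL17A and RORC held called CpGs again, with memory cells lower by 28.7, 15.7 and 28.2 points. With the donor as a replicate block the calls of the leading CpGs of IL10 at rest and IL17A after activation were lost (edgeR adjusted p = 0.0519 and 0.0843).

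Several genes held CpGs that differed in opposite directions. At rest ISG20, TP63, IFIT1 and MPZL2 each had CpGs lower and CpGs higher in memory than in naive cells. TP63 had 4 CpGs that were 23.9 points lower and 1 that was 28.6 points higher. Between CD19 and resting CD4 cells the myeloid peroxidase gene MPO had 1 CpG at 16.03% ± 1.19 (n = 4) against 78.8% ± 11.1 (n = 9) and another at 58.9% ± 8.14 against 30.4% ± 5.20. In CD8 against resting CD4 cells TOB1 had 1 CpG at 68.6% ± 7.92 against 94.96% ± 4.08 and 2 CpGs at 16.8% ± 8.48 against 2.45% ± 1.76. The replicate block ended the calls of the higher CpG of MPO and the leading higher CpG of TOB1 (edgeR adjusted p = 0.204 and 0.143).

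A hypothesis was that CpGs lower in memory lie in stretches with fewer CpGs than those higher in memory. Genes with lower CpGs had a mean of 3.88 ± 4.05 (SD, 113 genes) measured CpGs within 100 bp, and genes with higher CpGs 7.98 ± 4.71 (SD, 23 genes), with the 4 genes of both kinds left out (permutation p = 0.00013, 100000 permutations of genes). The values go with the hypothesis, for the CpGs that were measured. The genes were not matched by methylation level, with which the direction of the calls varied. At a mean level of 80% to 95%, 165 CpGs were lower and 5 higher in memory, against 33 and 47 at 5% to 20%. Whether CpG density matters apart from level was not tested. CpGs outside the amplicons were not counted.

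Another hypothesis was that activated naive cells may move toward memory methylation. At 638 CpGs that differed by at least 20 points, without overlap, between memory and naive libraries of run 88, naive cells of 2 other donors moved by 2.2 points on average, which is 7.1% (5.4% and 8.8%) of the 30.48-point distance. Both values lay between the bounds of 5% and 10% set for the test, so it decided neither way. Memory cells moved by 1.73 points away from naive cells, or 5.2% and 6.1% of the distance, and whether the naive and memory shifts differ was not tested.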
